A study of Danio rerio with 2 samples.

How the data were processed

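RNA was measured in whole zebrafish larvae from 2 pools, one kept in the solvent DMSO and one exposed to valbenazine at 10 µM. Per the labels' protocols, each pool held 50 larvae, total RNA was extracted with RNAiso Plus, and libraries were made with a SMARTER kit for mRNA sequencing. Valbenazine is a drug that blocks the vesicular monoamine transporter, which loads dopamine and serotonin into synaptic vesicles. Each group had 1 library, so the spread between replicates could not be measured, and no p-value, standard error or interval was computed.

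The authors deposited 1 signal track per library, a read depth for each window of 1000 bp. Each track lists 1345132 windows over 25 numbered chromosomes and the mitochondrial genome, with no gene names, no strand and no total read number. Every value is 0 or a multiple of 0.5, with 1 as the lowest value above 0, as a median of whole-number depths per base would give. The values show no scaling between the libraries. How the window value was computed, and the number of reads behind it, are not given in the sources used here. HISAT2 is named as the aligner, per the submitters' processing notes. The same notes name the mouse build mm10. The tracks do not have the chromosomes of mouse: their window counts equal the chromosome lengths of the zebrafish build GRCz11, rounded up to whole windows, for 25 of 25 chromosomes. Those lengths were taken from general knowledge of the assembly, and the comparison was made after the window counts had been seen. Positions are given on GRCz11, counted from 1. The last window of a chromosome may be shorter than its printed end. Within a library, 68.1% of covered windows in the DMSO control and 68.2% in valbenazine had exactly the value of the window before them.

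No GRCz11 gene annotation was used here. The gene table at hand is of another assembly, GRCz12tu, and on 24 of 25 chromosomes it places genes beyond the last window of the tracks, so its positions were not used. It served only for the order of the mitochondrial genes. Gene levels, the 49 gene lists fixed before the data were examined and the genes of the growth hormone and monoamine systems were therefore not analysed here, and the comparisons are of windows and loci.

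Both libraries were scaled to the same summed depth. A log2 ratio of valbenazine to DMSO was computed per window on scaled depth plus a pseudocount of 9.03, the median scaled depth of windows above 0 in either library. It understates differences at low depth. Windows with a mean scaled depth at or above the pseudocount were compared, and a difference of at least 2-fold was counted. The rule for naming items, fixed for genes before the data were examined, was applied to windows and took the 12 with the highest and the 12 with the lowest ratio. The remaining steps were chosen after seeing the data. Loci were runs of at least 3 adjacent windows with a scaled depth of at least 100, split where the depth of adjacent windows differed over 4-fold. A locus has the median ratio of its windows, and the quartiles given with it describe the spread along the locus, not replicate error. Windows of 1 locus can share reads and were not taken as independent. The 8 loci with the highest ratio, the 8 with the lowest and the 10 deepest are named or summarised. Deep blocks were runs of at least 20 adjacent windows with a scaled depth of at least 3000. For each chromosome the median ratio of its loci was set among 10000 random sets of as many loci matched on depth in 20 bins, as a description of these libraries. Windows whose value differed from both neighbours in both libraries were also examined alone, since runs of equal values may carry the same reads.

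The steps were tested on simulated data in which 200 of 4777 loci were changed. Of 50 loci simulated 3-fold higher and 50 simulated 3-fold lower, 100% were counted as different by at least 2-fold. The same held for 50 loci each way at 4-fold, and 0% of 4577 unchanged loci were counted. Values were drawn independently per window around the mean of the 2 libraries with counting noise alone, and scored at the loci already defined. Equal values of adjacent windows and variation between libraries were not simulated. The simulation therefore checks the computation and gives no error rate for the real tracks. Alternatives were median-ratio scaling, scaling to a trimmed mean of log ratios (TMM, with 30% of ratios and 5% of levels trimmed at each end), a pseudocount 4 times smaller or larger, no filter on depth and a filter 4 times higher. The named loci, blocks and mitochondrial windows were also computed under both other scalings. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.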

Results

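Whole-body RNA of zebrafish larvae exposed to 10 µM valbenazine was compared with that of larvae kept in DMSO, with 1 library of 50 pooled larvae per group. The study's title places the question in body growth and growth hormone signalling. The genes of that pathway were not analysed here, because the values are depths of genome windows and no gene annotation of their build was used. The summed window depth was 58693226.5 in the DMSO control and 61750003.5 in valbenazine. In the control 842279 windows of 1 kb (62.6%) had a depth above 0, with a median of 10 among them. In valbenazine these were 892128 windows (66.3%) with a median of 13. Signal was concentrated in few windows, and the 1000 deepest windows held 40.9% of the summed depth in the control and 34.2% in valbenazine. There were no replicates, so every difference below is one between 2 libraries, without a test.

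Relative to the deepest windows, weakly covered windows had more signal in the library of exposed larvae than in the control. Windows with a mean scaled depth of 10 to 30 had a median log2 ratio of 0.29 (230599 windows, median depth 14 in the control and 20 in valbenazine). The median was 0.25 at a depth of 30 to 100, 0.13 at 100 to 300, 0.07 at 300 to 1000 and 0.02 at 1000 to 3000. It was -0.15 in the 1013 windows with a depth of 3000 to 10000 and -0.26 in the 916 windows above that, whose median depth was 18922.5 in the control and 16795.5 in valbenazine. The difference between the lowest and highest class was 0.55. It was smaller, 0.36, in windows unlike both neighbours, with a median of 0.15 in the lowest class (26785 windows) and -0.21 in the highest (470 windows). Within single chromosomes, the median at 10 to 30 exceeded that at a depth of at least 3000 by 0.291 to 0.837, with a median of 0.453. This was largest on chromosome 9, where 240 of the 278 windows that deep belong to 1 block. The quartiles lay on either side of 0 in each class except at a depth of at least 10000, where they were -0.46 and -0.08. Where 0 falls depends on the scaling. With the median ratio of windows set to 1, which moves the log2 ratio before the pseudocount by -0.32, the lowest class was at 0.09, the next at -0.02 and the highest at -0.57, and the order of the classes was the same.

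**Figure D1:**
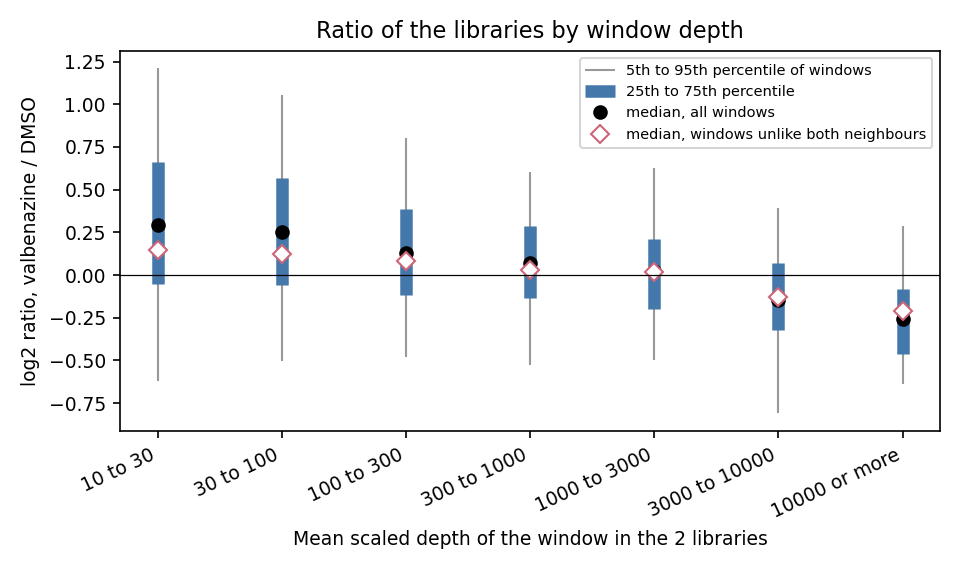
Log2 ratio of valbenazine to DMSO per 1 kb window (vertical axis) by the mean scaled depth of the window in the 2 libraries (horizontal axis, depth classes). Points are medians over windows, thick bars the quartiles, thin lines the 5th to 95th percentile, and open diamonds the medians of windows unlike both neighbours; the median goes from 0.29 in the lowest class to -0.26 in the highest.

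Of 480994 windows compared, 37163 (7.73%) were at least 2-fold higher in valbenazine and 5068 (1.05%) at least 2-fold lower, so that 88.0% of the differing windows were higher. Median-ratio scaling gave 16696 higher and 11659 lower windows, 58.9% of them higher, and TMM scaling, a trimmed mean of log ratios, 57.4% higher. With the pseudocount 4 times larger 1893 windows were higher and 1252 lower (60.2% higher), and among windows unlike both neighbours 2568 were higher and 1177 lower (68.6% higher). Of all windows, 119695 had a depth above 0 in valbenazine alone and 69846 in the control alone, with a median depth of 2 in each set, and 362 and 104 of them were deep enough to be among those compared.

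The 12 windows with the highest ratios had log2 ratios of 7.50 to 10.32. In order of their ratio they began at 44906001 on chromosome 11, 21621001 on 24, 67467001 on 7, 16229001 on 3, 42374001 on 10, 7444001 on 22, 1963001 on 5, 18546001 on 22, 30047001 on 21, 30507001 on 18, 42993001 on 19 and 19712001 on 23. The 12 windows with the lowest ratios reached -10.96, the least extreme being -8.70. They began at 44027001 on chromosome 10, 29097001 on 6, 3153001 on 22, 41312001 on 24, 29871001 on 3, 54211001 on 20, 46320001 on 14, 6270001 on 6, 23269001 on 1, 29086001 on 6, 39185001 on 21 and 3321001 on 25. On chromosome 11 the window had a depth of 2 in the control and 14507 in valbenazine, and on chromosome 10, at 44027001, a depth of 19458 in the control and 1 in valbenazine. The differences of these windows mostly did not extend to the windows beside them. Each of the 24 lay beside a window in which the library with the lower value was itself deeply covered, at a scaled depth of 2591 or more, and 1 of the 24 had a neighbour that differed at least 2-fold in the same direction.

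Loci were defined at a scaled depth of at least 100, where the balance of single windows was different. At a depth of 10 to 30, 10.1% of windows were at least 2-fold higher and 1.24% lower, against 1.96% and 0.76% at 100 to 300, 0.92% and 2.56% at 300 to 1000, 1.68% and 2.05% at 1000 to 3000 and 0.69% and 1.88% at 3000 to 10000. Of 4777 loci, with a median length of 8 kb, 4373 (91.5%) differed by less than 1.5-fold, 49 were at least 2-fold higher in valbenazine and 11 at least 2-fold lower. The direction turned with the scaling: 81.7% of these loci were higher, but under median-ratio scaling 21 were higher and 60 lower (25.9% higher), and under TMM scaling 24.4% were higher. The 60 loci that differed 2-fold had a median scaled depth of 130.3, near the limit of 100 for a locus, and a highest of 1728. Their depth was not compared with that of the other loci. Without the 10 loci that lay within 10 kb of a window at least 10 times deeper, 43 higher and 7 lower loci were left.

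Of the 8 loci with the highest ratios, 4 lay directly beside such a deeper run of windows. A 33 kb locus on chromosome 21 (7001 to 40000) had a median depth of 28 in the control and 300 in valbenazine (log2 ratio 3.05, quartiles 2.90 and 3.05), next to a run at a log2 ratio of -0.10. The others were on chromosome 7 (67477001 to 67483000, depth 0 and 651), chromosome 19 (5346001 to 5350000, depth 61 and 648) and chromosome 12 (17705001 to 17710000, depth 51 and 207). The windows of the chromosome 12 locus were uneven, with quartiles of the log2 ratio of 0.165 and 1.78. The remaining loci had no window at least 10 times deeper within 10 kb, and larger distances were not examined. On chromosome 20 (46586001 to 46595000) the depth was 77 in the control and 481 in valbenazine, a log2 ratio of 2.44. On chromosome 3 (26113001 to 26121000) it was 225 and 1112, a log2 ratio of 2.19. A second locus on chromosome 3 (57423001 to 57426000) went from 107.5 to 293.5 and one on chromosome 22 (336001 to 339000) from 308 to 1028.5, log2 ratios of 1.74 and 1.67. A longer locus of chromosome 3, chosen after its values were seen, was higher along 13 windows unlike their neighbours (23223001 to 23238000, depth 280 and 833, quartiles of the log2 ratio 1.04 and 1.41).

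Among the loci with the lowest ratios, the clearest case apart from deeper windows was on chromosome 6 (46242001 to 46249000). Its 7 windows had a median depth of 1353 in the control and 504 in valbenazine, a log2 ratio of -1.48 with quartiles of -1.49 and -1.40, and none equalled a neighbour. Less deeply covered loci were lower on chromosome 5 (51210001 to 51217000, depth 191 and 75) and chromosome 7 (26495001 to 26498000, depth 164 and 66). On chromosome 21 a 121 kb locus (20778001 to 20899000) had a depth of 232 and 101, and most of its windows equalled a neighbour. The other 4 of these 8 loci lay beside deeper runs: 73 kb on chromosome 9 (54105001 to 54178000, depth 230 and 2, log2 ratio -4.48), 270 kb on chromosome 14 (46034001 to 46304000, depth 688 and 25, log2 ratio -4.41), 57 kb on chromosome 15 (49001 to 106000, depth 2273 and 690, log2 ratio -1.77) and 19 kb on chromosome 18 (17001 to 36000, depth 194 and 71, log2 ratio -1.39). The deeper runs next to the loci on chromosomes 9, 14 and 15 had log2 ratios of -0.34, -0.06 and -0.14, and that on chromosome 18 had one of 0.39, opposite in direction to its locus.

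**Figure D2:**
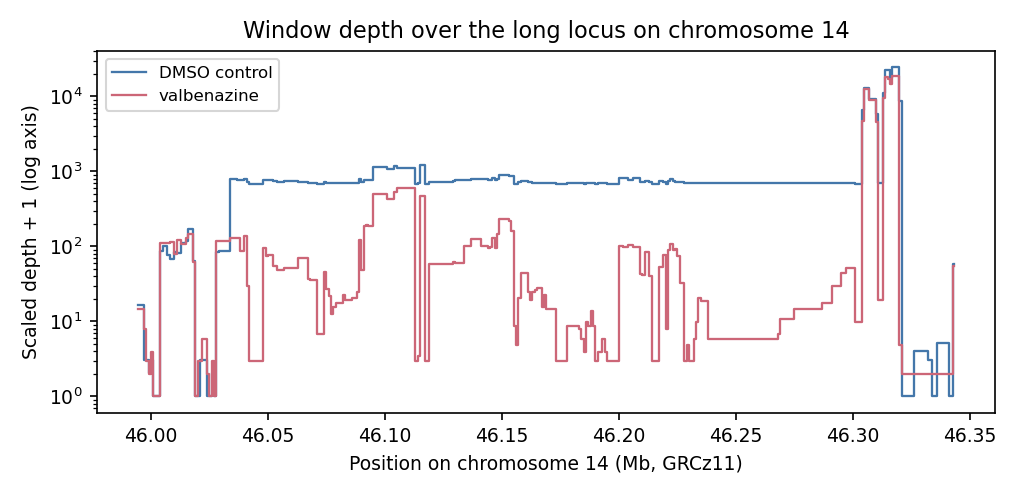
Scaled depth plus 1 (vertical axis, logarithmic) per 1 kb window along chromosome 14 (horizontal axis, Mb, GRCz11) in the DMSO control and valbenazine. From 46034001 to 46304000 the control stays near its median scaled depth of 706 while valbenazine moves with the local features around a median of 24.4, and the deep run to the right is alike in both libraries.

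Most of the deepest loci had a lower share of the signal after exposure. Of 210 loci with a scaled depth of at least 3000, 154 had a ratio below 0 and 56 above 0, with a median log2 ratio of -0.175, and 0 differed by 2-fold. Under median-ratio scaling 207 were below 0 and 3 above. By the mean scaled depth of the 2 libraries the deepest locus was on chromosome 17 (117001 to 125000). Its median depth was 138856 in the control and 141831 in valbenazine, and the median log2 ratio of its 8 windows was -0.17. Depths and ratio are separate medians over windows, so the ratio need not follow from the depths. The next deepest was a locus on chromosome 3 (61194001 to 61206000), with 155521.5 and 119049.5 and a log2 ratio of -0.31. Of the 10 deepest loci, that on chromosome 9 (56228001 to 56231000) had the lowest ratio, -0.43, with depths of 47796 and 37427. The locus on chromosome 19 (43119001 to 43122000) had the highest, 0.065 over its 3 windows (quartiles 0.037 and 0.218), and -0.256 under median-ratio scaling. Its median depths were 42150 and 57376.5, and its ratio does not follow from them.

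The longest block of deep windows spanned 240 kb of chromosome 9 (22099001 to 22339000). It held 4.95% of the summed depth of the control and 3.44% of that of valbenazine. The median depth was 12016 and 8799, and 208 of the 240 windows were lower in valbenazine, with a median log2 ratio of -0.59 (quartiles -0.65 and -0.41). Its 22 windows that differed from both neighbours gave -0.58. Most of the block is runs of equal values between short peaks. Its right end (22318001 to 22339000) was taken from the last window lower in valbenazine onward, so that all its 21 windows were higher by construction. Their log2 ratios were nearly equal (0.095 to 0.104), with a median of 0.10, which was -0.22 under median-ratio scaling. Under that scaling the ratio of the whole block was -0.91 and all 240 windows were lower.

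**Figure D3:**
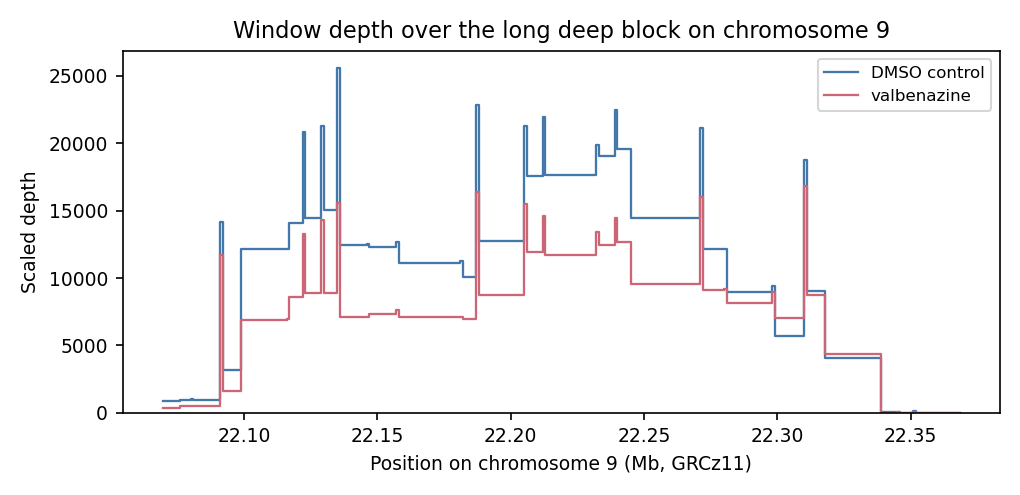
Scaled depth (vertical axis) per 1 kb window along the block on chromosome 9 (horizontal axis, Mb, GRCz11) in the DMSO control and valbenazine. Valbenazine lies below the control in 208 of 240 windows of the block, at peaks and at the runs of equal depth between them, and above it in the last 21 windows, which lie below 0 under median-ratio scaling.

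Among the other blocks, one of 31 kb on chromosome 19 (5350001 to 5381000) had a median depth of 32675 in the control and 22119 in valbenazine, a log2 ratio of -0.51, and one of 20 kb on chromosome 15 (88001 to 108000) had 5310 and 2875, a log2 ratio of -0.96. The latter overlaps the locus beside a deeper run described above. Blocks on chromosome 6 (55032001 to 55081000), chromosome 5 (71700001 to 71722000) and chromosome 2 (50999001 to 51031000) had log2 ratios of -0.33, -0.28 and -0.19. Ratios above 0 were found in blocks on chromosome 5 (32212001 to 32234000, depth 9083 and 11611, log2 ratio 0.28; and 32263001 to 32305000, log2 ratio 0.155) and chromosome 2 (57149001 to 57175000, log2 ratio 0.145). Under median-ratio scaling these 3 blocks were below 0 as well, at -0.04, -0.165 and -0.18. In windows unlike both neighbours the first of them was at 0.20, but the other two were both at -0.05. In such windows the blocks on chromosomes 19 and 6 were at -0.35 and -0.18, nearer to 0 than over all their windows.

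Chromosomes as a whole differed little. Chromosome 9 had the largest shift, from 7.70% of the summed depth in the control to 6.25% in valbenazine, a log2 ratio of -0.30. Outside the deep block its share was 2.74% and 2.82%, a log2 ratio of 0.04. Chromosome 4 had the largest rise in share, from 1.95% to 2.23% (log2 ratio 0.19). The median ratio of the loci on a chromosome lay between 0.04 and 0.12, and on 0 of 25 chromosomes did it lie among the lowest or the highest 2.5% of medians of random loci matched on depth.

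The mitochondrial genome held a similar share of the summed window depth in both libraries, which need not be its share of reads or RNA. The 17 windows of the mitochondrial genome held 0.415% of the summed depth in the control and 0.387% in valbenazine, a log2 ratio of -0.10. Its genes for parts of the respiratory chain follow in an order that runs from ND1, ND2 and COX1 over COX2, ATP8, ATP6 and COX3 to ND5, ND6 and CYTB, after the ribosomal RNA genes mt-rnr1 and mt-rnr2. The deepest window (7001 to 8000) had a depth of 73229 in the control and 69115 in valbenazine, a log2 ratio of -0.16. Windows with higher ratios were at 13001 (depth 1875 and 2820.5, log2 ratio 0.51), 3001 (481.5 and 720.5, log2 ratio 0.50), 14001 (log2 ratio 0.39) and 11001 (log2 ratio 0.30). The lowest ratios were -0.35 at 1 and -0.34 at 1001. Of 17 windows 7 were above 0, but 3 under median-ratio scaling, those at 3001, 13001 and 14001.

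**Figure D4:**
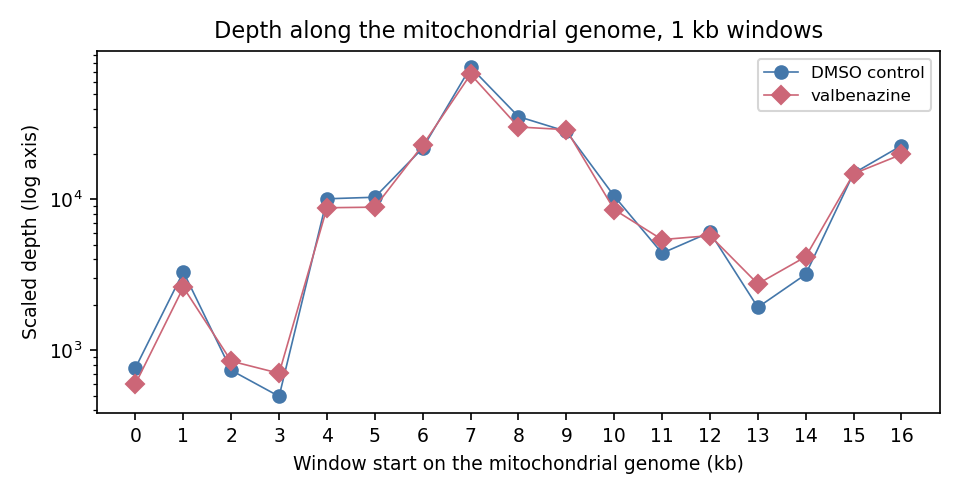
Scaled depth (vertical axis, logarithmic) in the 17 windows of the mitochondrial genome (horizontal axis, window start in kb) in the DMSO control and valbenazine. The profiles follow each other closely, with the deepest window at 7001 to 8000 in both libraries and the highest ratios of valbenazine to DMSO at 3001 and 13001.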

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

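Each group has 1 library, so no replicate could be left out. No paired analysis was possible for the same reason. The alternatives planned for gene levels, the gene lists and the growth hormone genes were not run, since no gene annotation of the build was used. The alternatives based on windows unlike their neighbours, on neighbours that differ the same way, on other locus limits and on distance from deeper windows were chosen after seeing the data. The direction of the counts rests on scaling. Windows at least 2-fold higher and lower numbered 37163 and 5068, but 16696 and 11659 under median-ratio scaling and 16283 and 12078 under TMM scaling. Loci numbered 49 higher and 11 lower, but 21 and 60 under median-ratio scaling and 20 and 62 under TMM scaling. The ratio of the chromosome 9 block was -0.59, then -0.91 and -0.92. These scalings move the log2 ratio before the pseudocount by -0.32 and -0.33, which shifts the counts from higher to lower. A pseudocount 4 times smaller gave 74110 higher and 11685 lower windows, and one 4 times larger gave 1893 and 1252 windows and 26 higher loci. A depth filter 4 times higher, which leaves fewer windows, gave 8447 higher and 1579 lower. Windows unlike both neighbours, a smaller set, gave 2568 higher and 1177 lower windows and 17 higher loci. Requiring neighbours that differ the same way left 26234 higher and 2507 lower windows (91.3% higher). Loci numbered 155 higher and 26 lower at a depth of at least 50, 21 and 5 at a depth of at least 200, and 30 higher with at least 6 windows. Without loci near deeper windows 7 lower loci were left. The fall of the ratio with depth kept its direction under the 4 alternatives of scaling and pseudocount and in windows unlike both neighbours, between 0.36 and 0.67. The ratios of the 24 named windows are too large for these alternatives to turn, and the pseudocount moved their size in 23 of 24 windows when smaller and in 24 of 24 when larger. Beyond what the construction of an alternative shows, the cause was not tested. The number of reads is unknown, and most windows covered in 1 library alone, with a median depth of 2, were too shallow to be among those compared.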

Other observations

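The tests reported here were chosen after the result was seen, those of the fall of the ratio with depth included, for which the values over all windows were known.

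Chromosome 4 was covered unevenly in both libraries. Between 30000001 and 70000000 only 33.5% to 38.0% of windows had a depth above 0 in the DMSO control and 38.8% to 45.5% in valbenazine. In the first 30 Mb these shares were 64.1% to 76.5% and 67.3% to 77.4%, and from 70000001 to the end 73.6% and 77.9%. The summed depth of the 10 Mb from 40000001 was 9241 in the control and 11795.5 in valbenazine, against 439522 and 489271 in the first 10 Mb. In the 10 Mb from 30000001 the 353 windows compared had a median log2 ratio of 1.08, against 0.26 to 0.29 in the first 30 Mb, and the other steps of this region had -0.14 to 0.46 over 68 to 606 windows.

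The first pattern is the 24 windows with the largest ratios. If they marked a change of the RNA of their neighbourhood, neighbouring windows should differ too, but 1 of the 24 had a neighbour that differed at least 2-fold the same way, which argues against it. In 24 of 24, a neighbouring window was deep in the library with the lower value. A candidate explanation is that a window value is a median over covered bases alone: at the edge of a deep locus it switches between the depth of the locus and a depth of 1 or 2 when a few reads cover the remaining bases.

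The second pattern is the 60 loci that differ at least 2-fold, of which 10 (16.7%) had a window at least 10 times deeper within 10 kb, against a mean of 2.45% in 10000 random sets of other loci matched on depth, of which all but the highest 2.5% were at or below 6.67%. On chromosome 15 the locus left of such a run (24858 in the control and 23786.75 in valbenazine) was lower, 2273 and 690, and the locus right of it higher, 783 and 2338. On chromosome 14 the scaled control exceeded valbenazine by a median of 684, with an interquartile range of 2.0% of that median over 270 windows, while the log2 ratio without pseudocount had an interquartile range of 3.69, which argues against a fall of all features inside by one common ratio, though falls of differing size stay open and valbenazine was shallow there. A candidate explanation is gapped alignments from the deeper run, counted at every skipped base, but a nearly constant difference alone does not mark them. On chromosome 21 (20778001 to 20899000), with no window 10 times deeper within 10 kb, both the difference (1.99%) and the ratio (0.07) were nearly constant. For the other 50 loci the length of alignment gaps is not known from the tracks, and such alignments cannot be told apart from a change of the locus itself.

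The third pattern is the fall of the ratio with depth, from weakly covered windows to the deepest ones. A single scaling factor moves all ratios alike and leaves no such fall. The fall was 0.705 without a pseudocount, a value no scaling changes while windows keep their depth classes from library-total scaling. A difference in sequencing depth was not tested. The number of reads is unknown, and a median over covered bases need not follow it in proportion. If depths add up, equal extra coverage everywhere, as from genomic DNA, would as the whole cause add the same depth at 100 to 300 as at 10 to 30. With the scale set by windows of at least 3000, the added depth was over 1.5 times larger on 25 of 25 chromosomes (1.82 to 7.13 times, with 14 deep windows on chromosome 17). Without that scale the comparison turned with the scaling, with 23 of 25 chromosomes over 1.5 times under the library total and 0 under median-ratio and TMM scaling. Medians over covered bases need not add up in this way, so extra coverage of this kind is not excluded. Coverage counted over alignment gaps is not excluded either. The fall was smaller, 0.362, in windows unlike both neighbours, but local reads on top of a gap also make a window differ. At the chromosome 14 locus 49 such windows still had depths of 712 and 62, a log2 ratio of -3.435. What stays open is a change of the most abundant transcripts by the exposure, a different make-up of the pools, library preparation, sequencing depth, extra background coverage or alignment gaps. With 1 library per group these cannot be told apart.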
